A study of Homo sapiens with 10 samples.

How the data were processed

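Cells that carried the interleukin-11 receptor (IL-11R) on their surface were sorted from untreated patients with relapsing-remitting multiple sclerosis, and their RNA was counted cell by cell in 10 libraries from 5 donors. In the IL-11 experiment, sorted blood cells of donors 1 to 3 were kept unstimulated or given recombinant IL-11 at 100 ng/ml for 1 h. In the fluid experiment, sorted cells came from blood and from cerebrospinal fluid (CSF) of donors 4 and 5. The labels name the same patient for both libraries of each pair, so both experiments were treated as paired by donor. Per the labels, the samples of each experiment were submitted for sequencing on 1 day. The IL-11 and CSF libraries have no donor in common and were not compared with each other except where a correlation across genes is given.

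The deposited matrices hold raw counts, that is, unique molecular identifiers (UMIs) per gene and cell barcode, that the authors made with Cell Ranger 5.0.0 on GRCh38 from 10x Genomics 3' v3 libraries. They list 36601 genes, of which 34616 identifiers have an entry in GENCODE 29, the source of all coordinates. The authors' list of barcodes was taken as given. UMI totals ran from 6420636 to 25642103 per library over 681 to 5962 barcodes.

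Barcodes with at least 200 detected genes and under 15% mitochondrial UMIs were kept. Scrublet, as run in scanpy 1.11.5, was used to remove likely doublets within each library. Its automatic threshold marked as few as 0.0169% and at most 1.96% of a library's cells, so the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes. That rule was chosen after the scores had been seen. It left 658 to 5634 cells per library, with a median of 3809 to 9864 UMIs before doublets were removed.

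Within each experiment, counts were scaled to a common total and log-transformed, 2000 variable genes were reduced to 30 principal components, and cells were joined by 15 neighbours and clustered by the Leiden method at resolution 1 with seed 1, using leidenalg 0.10.2 and igraph 0.11.9 under Python 3.11.15. Each cluster was named from marker genes of 18 cell types, by the markers among its 10 leading genes and the mean scaled level of each marker set. T-cell clusters were parted by their CD4, CD8 and FOXP3 counts. Clusters with no clear name stayed unnamed. Clusters named classical monocyte, nonclassical monocyte or macrophage were pooled as monocyte-like cells, and those named CD4 T or regulatory T as CD4 T-like cells. The names describe marker RNA and no surface protein was measured.

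UMI counts were summed per library and class, and a class was tested where every library of at least 2 donor pairs held 20 cells or more. Genes passed the filterByExpr filter of edgeR 4.0.16. Normalization was by the trimmed mean of M values (TMM). The quasi-likelihood F test was fitted with donor as a block under R 4.3.3. Adjusted p values are Benjamini-Hochberg values within a class, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size over the square root of the F statistic. The paired design left 2 residual degrees of freedom in the IL-11 experiment and 1 in the fluid experiment, and edgeR pools the spread of each gene with that of other genes. Changes within a donor were computed with a prior count of 1. A difference in IL-11 response between monocyte-like and CD4 T-like cells was tested as an interaction, with library as a block. Levels are given as CPM, the UMI counts of a gene scaled to a common library total with TMM factors, as mean ± SD over libraries. Removed from naming and tests were 546 receptor gene segments, which follow clones. Another 103 genes (Y-linked, and XIST with its antisense partner) were left out of every table.

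A set of 29 gene lists and the markers were fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Lists with at least 5 measured genes were tested by camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation, camera tests on the residual degrees of freedom of the fit, 2 or 1 here, so hardly any list can pass. A call lost in that setting therefore cannot decide whether the list changed. For each list the number of members called over all genes tested stands beside the number called when adjusted over the list alone. The naming rule took, in each of the 4 main comparisons, up to 10 called genes with the largest rise and 10 with the largest fall that moved the same way in every donor at a mean of at least 20 CPM. Where fewer than 5 genes met this, it took the 5 with the smallest p in each direction. It added 15 genes of the IL-11, inflammasome, S100 and VEGF systems whatever their values, and up to 4 members of each called list. In other classes it took 3 in each direction. Genes that define a class were not named within it. The sterol gene list of the closing section was written after some of its members had been seen.

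For a gene at 0 counts in every library of a group, the fold is a bound against 3 counts over that group. With 1 to 3 counts, the ratio of CPM over the pooled libraries is given with an exact 95% counting interval. Shares of cells have exact Clopper-Pearson 95% intervals, and paired shares in the IL-11 experiment were compared by a two-sided exact sign-flip permutation test. Intervals and bounds cover counting error and leave out differences between donors. For IL11RA, each cell was thinned to 2000 UMIs, and shallower cells were left out of that share.

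The test was tried on simulated data, drawn from a negative binomial distribution with the donor means, library sizes and gene dispersions of each main comparison, with 192 to 199 measured genes changed. In monocyte-like cells it recovered 88% of 2-fold changes in the IL-11 design and 30% in the CSF design. In CD4 T-like cells it recovered 79.6% and 70.2%. False calls were 11.2%, 2.65%, 6.78% and 4.83% of those made, in the same order. Genes were drawn independently and each changed gene had the same fold in every donor. These rates therefore do not cover changes that differ between donors.

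Alternatives were relative log expression size factors, DESeq2 1.42.0, no filter on low counts, no donor block, each donor left out, at least 500 genes per cell, under 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, at least 50 cells per library, counts thinned to the smallest total, all 10 libraries in 1 fit, classical monocyte-like clusters alone, and CD4 T-like clusters without regulatory ones. Added after seeing the data were robust empirical Bayes, a single CD4 T-like cluster, barcodes kept only in the library where they are deepest, and a fit without genes over 10 times higher in another class. Libraries of the same group were checked for copies of each other. The chi-square per degree of freedom between their gene totals ran from 45.3 to 330, far above that of a copied library.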

Results

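The data are RNA counts of single cells that were sorted for surface IL-11R, the receptor of the cytokine interleukin-11. The 10 libraries came from 5 donors with relapsing-remitting multiple sclerosis. Donors 1 to 3 gave 3 unstimulated and 3 IL-11 libraries from blood, which address what IL-11 changes within 1 h, with the NLRP3 inflammasome as the stated subject of the series. Donors 4 and 5 gave 2 blood and 2 CSF libraries, which address how receptor-bearing cells of the central nervous system fluid differ from those of the blood. UMI totals of the unstimulated libraries were 24809935, 19637257 and 10886326 for donors 1 to 3, and those of the IL-11 libraries were 19164303, 16287197 and 9521109. Donor 4 had 15212608 UMIs in blood and 25642103 in CSF, and donor 5 had 21843086 and 6420636. The cells used numbered 3874, 2746 and 1439 without IL-11, 2201, 2678 and 1418 with it, 2129 and 3394 in blood, and 5634 and 658 in CSF. Between 0.608% and 28.6% of a library's cells lay in clusters that could not be named, with the highest share in the IL-11 library of donor 3.

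RNA of the receptor was found in few of the sorted cells of any class, and differences between classes were not tested. IL11RA, which encodes the ligand-binding chain of the receptor, lies on chromosome 9 from 34650702 to 34661892 in GRCh38 (ENSG00000137070). At a common depth of 2000 UMIs per cell, 2.85% ± 0.843 (SD, n = 10 libraries) of CD4 T-like cells and 1.05% ± 0.472 (n = 10) of monocyte-like cells held an IL11RA UMI. The CD4 T-like share was the higher in 9 of 10 libraries, with 0.881% against 1.14% in the unstimulated library of donor 2. The share was 1.87% ± 1.32 (n = 9) in CD8 T-like, 1.32% (from 0 to 3.33% over libraries, n = 9) in B-like and 1.12% ± 1.90 (n = 9) in NK-like cells. Too few plasma cell-like and neutrophil-like cells reached that depth to measure a background in a library, with 4 to 57 and 3 to 158 per library. At 3 counts, their counts of 0 allow 5.26% and 1.90% in the library with the most such cells, and more in the others. A background near the monocyte-like share is therefore not excluded in any single library. Unthinned, 1.08% and 0.221% of these cells held an IL11RA UMI. Neutrophil-like cells were shallow, with a median of 1217 to 1326 UMIs in the 3 libraries measured, against 3986 to 7379 in CD4 T-like and 6559 to 10919 in monocyte-like cells. Summed levels were 14.7 ± 2.83 CPM in CD4 T-like cells and 5.02 ± 1.46 CPM in monocyte-like cells (n = 10). Over all cells, 1.64% ± 0.517 (n = 10) had an IL11RA UMI when thinned, so the RNA was seen in few of the cells that had been sorted on the protein.

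After IL-11, the mix of sorted cells moved in opposite ways in different donors. Monocyte-like cells went from 13.55% (exact 95% interval 12.49 to 14.67) to 46.43% (44.33 to 48.54) of the cells of donor 1. They went from 45.85% to 23.82% in donor 2 and from 56.78% to 31.31% in donor 3. CD4 T-like cells moved the other way, from 31.88% to 14.68% in donor 1, from 8.41% to 19.31% in donor 2 and from 12.65% to 16.43% in donor 3. The paired monocyte-like difference averaged -4.87 percentage points (SD 32.7, n = 3), with an exact two-sided sign-flip p of 1, where 3 pairs can give no p below 0.25. Plasma cell-like, dendritic cell-like and unnamed shares were higher with IL-11 in 3 of 3 donors, each with an exact p of 0.25, the smallest possible. Cells named neutrophil-like made up 28.0% and 27.4% of the libraries of donor 2 and at most 2.26% of the other IL-11 experiment libraries. Clusters of 833 and 33 cells, before doublets were removed, also scored highest for neutrophil markers. They stayed unnamed for their low UMI counts, and these shares leave them out. Unnamed cells made up 15.84% and 28.63% of the libraries of donor 3 without and with IL-11.

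**Figure D1:**
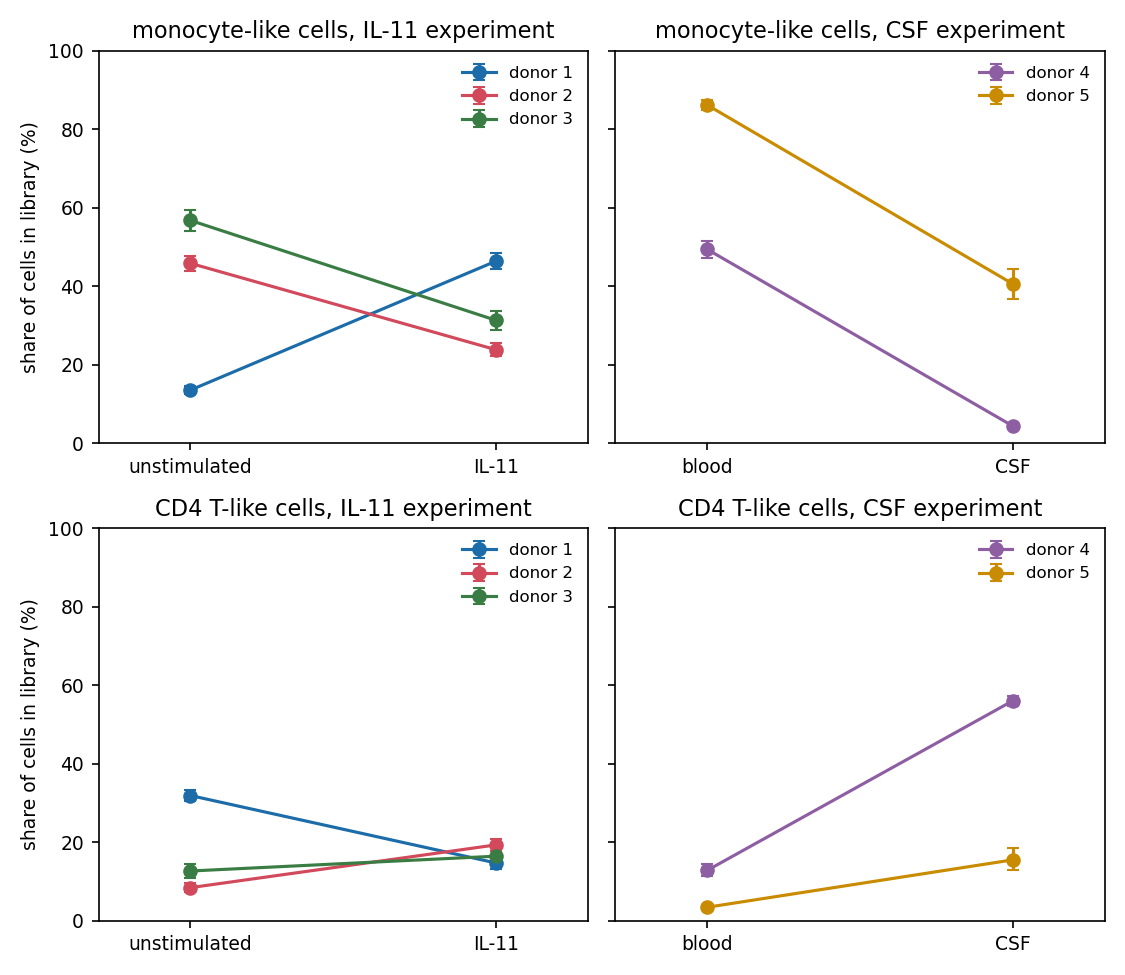
Share of monocyte-like and CD4 T-like cells (percent of cells used) in each of the 10 libraries, with exact 95% intervals as bars; lines join the 2 libraries of a donor. Monocyte-like cells rise from 13.55% to 46.43% in donor 1 after IL-11 and fall in donors 2 and 3, and they are fewer in CSF than in blood in donors 4 and 5.

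In monocyte-like cells, no inflammasome gene was called between IL-11 and unstimulated libraries. In the simulated data this fit recovered 36.7% of 1.5-fold changes, so small changes can be missed. The simulated changes were equal in all donors, whereas here donor 1 moved against donors 2 and 3. Larger changes may be missed as well. NLRP3 (ENSG00000162711, chromosome 1, 247416156 to 247449108), the sensor protein of the complex, had 816 ± 393 CPM without and 780 ± 443 CPM with IL-11 (SD, n = 3 donors), a log2 fold change of -0.09 with an SE of 0.16. The interleukin gene IL1B had -0.10 (SE 0.18), IL18 had -0.21 (SE 0.20), and CASP1, which encodes the protease that matures both products, had -0.05 (SE 0.13). SOCS3, a feedback gene of STAT3 signalling, had 0.05 (SE 0.15), and STAT3 itself had -0.09 (SE 0.12). NFKB1, NFKBIA, PYCARD, S100A8, S100A9, IL11RA and IL6ST lay between -0.08 and 0.06, VEGFA and VEGFB at -0.27 and -0.24.

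By edgeR, 0 of 11770 genes were called in monocyte-like cells, with 162 at an unadjusted p under 0.05 and 0 by DESeq2. The smallest adjusted p was 0.0964, of the haemoglobin gene HBB at 4.53 CPM, named after its value was seen. The 5 genes with the smallest p in each direction among those with a mean of at least 20 CPM did not pass either. They included the immunoglobulin genes IGLC3 (2.55, SE 0.44, adjusted p = 0.516) and IGHM (2.17, SE 0.46), whose RNA is abundant in plasma cells, and the itaconate-producing enzyme gene ACOD1 (0.72, SE 0.18). C11orf96 (0.64) and the interferon-stimulated gene IFI27 (0.71) were the other positive ones. The negative ones were the monocyte-attracting chemokine CCL2 (-0.86, SE 0.21), CCRL2 (-0.48), EMP1 (-0.55), PRDM1 (-0.62) and RALGDS (-0.48). Donor 1 opposed the others: without donor 1, 191 genes were called, against 2 without donor 2 and 5 without donor 3. Classical monocyte-like clusters alone gave 10 calls, and these clusters followed donors, since a cluster led by EREG, NLRP3 and IL1A lay mostly in donor 1 (294 and 778 cells without and with IL-11), one led by CCL20 and PTX3 in donor 3 (541 and 208), and one led by TMEM176B and SIGLEC1 in donor 2 (787 and 320).

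Of 27 gene lists tested in monocyte-like cells, 3 were called, all lower after IL-11, and none of their members passed alone. NF-kB pathway and target genes (25 measured) had a median log2 fold change of -0.07 (adjusted p = 0.0229), with BIRC3 at -0.47, NFKBID at -0.36, CD83 at -0.28 and NFKB2 at -0.20. Migration and angiogenic genes (27 measured) had a median of -0.10 (adjusted p = 0.0340), with the chemokine receptor CCR1 at -0.31 but CXCR2 at 0.47. Complement genes (19 measured) had a median of -0.12 (adjusted p = 0.0340), with C3AR1 at -0.32, C1QB at -0.42, C1QC at -0.92 and C5 at -0.50. Each call was lost at adjusted p = 0.979 with an estimated correlation, and 0 lists were called when no donor block was used. Adjusted over the list alone, 0 members of these 3 lists passed, and 3 inflammatory cytokine genes passed as lower. The inflammasome list (22 measured) had a median of -0.07 (adjusted p = 0.108) and the gp130 and STAT3 list (24 measured) a median of -0.08 (adjusted p = 0.108), so neither was called.

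In CD4 T-like cells, edgeR called a few genes after IL-11 that moved the same way in 3 of 3 donors, and the calls depended on the settings. GADD45B (ENSG00000099860, chromosome 19, 2476122 to 2478259), a stress-inducible regulator of MAP kinase signalling, rose from 125 ± 12.6 to 172 ± 3.79 CPM (SD, n = 3), a log2 fold change of 0.47 (SE 0.09). FAM177A1 (ENSG00000151327, chromosome 14, 35044907 to 35113130) rose from 129 ± 18.2 to 186 ± 66.7 CPM, at 0.53 (SE 0.10). TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), which binds thioredoxin and belongs to the fixed inflammasome list, fell from 782 ± 176 to 589 ± 132 CPM, at -0.41 (SE 0.07). IGLC3, an immunoglobulin light chain gene under 20 CPM that was named only after its value was seen, rose by 1.35 (SE 0.25). It was a leading gene of the plasma cell-like cluster, whose share was higher with IL-11 in 3 of 3 donors. The inflammasome and receptor genes gave no call: NLRP3 had 0.16 (SE 0.34) at about 8 CPM, IL1B 0.27 (SE 0.28, but past the threshold at -1.10 without donor 1 and at 0.68 without donor 2), CASP1 -0.16 (SE 0.13), PYCARD 0.09, IL11RA -0.15 (SE 0.21), IL6ST -0.07, SOCS3 0.09 (SE 0.11), STAT3 -0.02, NFKB1 0.22 (SE 0.10), NFKBIA -0.01 and VEGFB -0.11.

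These 4 genes (3 higher, 1 lower), each at an edgeR adjusted p of 0.0387, were the calls among 8960 genes tested in CD4 T-like cells, with 466 at an unadjusted p under 0.05. DESeq2 called 0, with 28 at an unadjusted p under 0.05, and 0 were called by edgeR without the donor block or with relative log expression size factors. The count was also 0 with doublets kept, at Leiden resolution 2, with counts thinned and with all 10 libraries in 1 fit. It was 18 without the filter on low counts and 10 without genes over 10 times higher in another class. Without donor 1, 2 or 3 the counts were 7, 44 and 0, and GADD45B, FAM177A1 and TXNIP passed without donor 2 but not without donor 1 (adjusted p = 0.591, 0.838 and 0.0955) or donor 3 (each 1.00). Below the threshold lay RASGEF1B (0.55, adjusted p = 0.0841), ZNF331 (0.53, adjusted p = 0.0874), SNAPC1 (0.86), the AP-1 gene FOSL2 (0.59) and the phosphatase gene DUSP2 (0.37), and on the negative side KLF6 (-0.40, adjusted p = 0.103), AC020916.1 (-0.36), FOS (-0.30), C1orf162 (-0.36) and CALHM6 (-0.71). S100A8 had 1.02 (SE 0.25, adjusted p = 0.217) and S100A9 0.68 (SE 0.27). In donor 1, whose S100A8 difference was 2.67, myeloid cells held 19.7% of the UMIs without and 57.8% with IL-11. In donor 2 that share fell from 72.2% to 43.0%, while S100A8 rose from 175 to 216 CPM (without TMM factors). In donor 3 the share fell from 71.7% to 47.7% and S100A8 from 25.8 to 21.6 CPM. S100A8 thus did not follow the myeloid share in every donor.

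**Figure D2:**
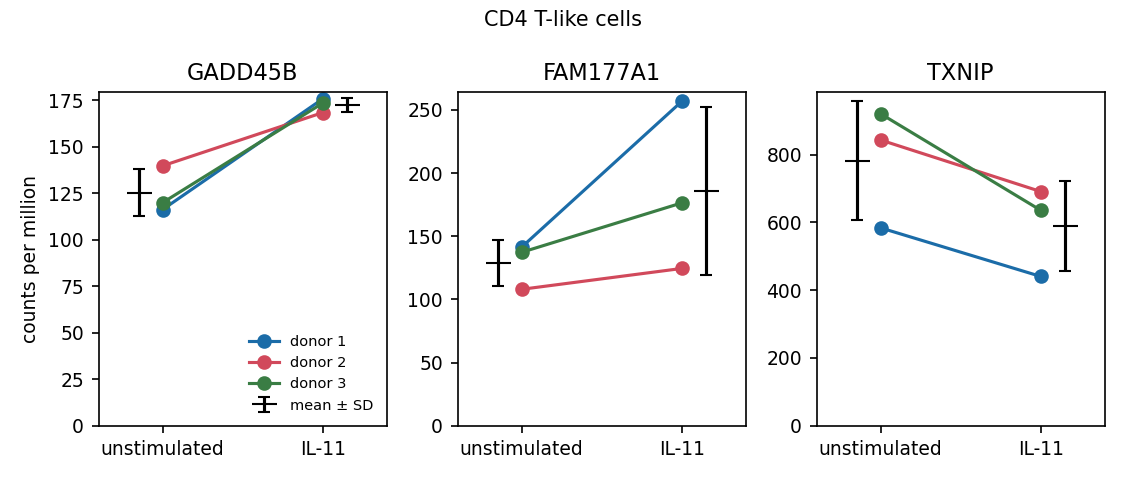
Levels of GADD45B, FAM177A1 and TXNIP in CD4 T-like cells (CPM) without and with IL-11; points are the 3 donors joined by lines, and bars give the mean ± SD. GADD45B goes from 125 to 172 CPM, FAM177A1 from 129 to 186 CPM and TXNIP from 782 to 589 CPM on average.

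No gene list of the 23 tested in CD4 T-like cells was called. Of 24 immediate-early genes measured, 1 (GADD45B) was higher, and adjusted over the list alone 5 were higher and 4 lower, with a median of -0.02 and a mean of 0.07. Of 14 inflammasome genes, 1 (TXNIP) was lower, also when adjusted over the list alone, while the list's median and mean of 0.02 and its camera direction differed in sign (adjusted p = 0.323). Of 25 gp130 and STAT3 genes, 0 passed, with a median of 0.03. Heat shock genes had a median of -0.11 (adjusted p = 0.163). The response did not differ detectably between monocyte-like and CD4 T-like cells: 0 of 12512 genes passed the edgeR interaction test, with 174 at an unadjusted p under 0.05, and 1 passed without donor 1.

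In the other classes, IL-11 gave 12 calls. Plasma cell-like cells had 9 of 4067 (3 higher, 6 lower). RRM2, which encodes a ribonucleotide reductase subunit, fell, at -2.59 (SE 0.34, adjusted p = 0.00425), as did TYMS, the thymidylate synthase, at -1.54 (SE 0.24), and the histone gene HIST1H1B at -1.89 (SE 0.34). The chaperone gene HSPA1A rose by 1.75 (SE 0.26), MDM2, which encodes the ligase that limits p53, by 1.09 (SE 0.21), and CITED2 by 1.08 (SE 0.20), all in 3 of 3 donors. Of 19 cell cycle genes, 4 fell, 12 when adjusted over the list alone, with a median of -1.11 (camera adjusted p = 7.77e-39, and adjusted p = 0.667 with an estimated correlation). These libraries held 23 to 83 plasma cell-like cells each, and 152 of their 252 barcodes were also held by another library of the experiment. Of the 252, 115 had a deeper copy in another library. Cells deep enough for the IL11RA share numbered 18 and 9 in donor 1 without and with IL-11. They numbered 28 and 57 in donor 2, and 4 and 17 in donor 3. The directions in donors 1 and 3 therefore rest on few deep cells, and the minimum of 20 cells was met partly through shallow copies. With each barcode kept only in its deepest library, or with at least 500 genes per cell, too few plasma cell-like cells were left for a fit. HSPA1A is over 10 times higher in another class. Without donor 2, 5 of the 6 named plasma cell-like genes no longer passed, RRM2 being the exception. B-like cells had 3 of 6075 called, all higher, of which 1, the early response gene IER3, moved the same way in 3 of 3 donors (1.98, SE 0.38, adjusted p = 0.0449). The others, named after their values were seen, were the chemokine genes CCL3L1 (1.89, SE 0.30) and CCL3 (1.35, SE 0.25), whose direction differed between donors. All 3 are over 10 times higher in another class, and with such genes left out 0 of 5832 genes were called in B-like cells. edgeR called 0 of 6100 genes in CD8 T-like cells (278 at an unadjusted p under 0.05) and 0 of 5009 in NK-like cells (167). DESeq2 called 0, 0 and 0 in CD8 T-like, NK-like and B-like cells and 1 in plasma cell-like cells. Leaving out donor 1, 2 or 3 gave 19, 56 and 62 calls over these classes, and no replicate block gave 0.

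In CD8 T-like, NK-like and B-like cells, gene lists were called at the preset correlation with almost no single member passing. With an estimated correlation 0 lists were called in each. In CD8 T-like cells 4 of 23 lists were called, NF-kB genes higher (median 0.24, adjusted p = 1.04e-05, 3 of 21 higher when adjusted over the list alone) and cytotoxic effector (median -0.21), heat shock (-0.18) and NK marker genes (-0.22) lower. All 4 had adjusted p = 0.761 with an estimated correlation. In NK-like cells 3 of 22 lists were called, inflammatory cytokines higher (median 0.07) and heat shock (-0.11) and ribosomal protein genes (-0.07) lower, each at adjusted p = 0.809 with an estimated correlation. In B-like cells 6 of 21 were called. Inflammatory cytokines (median 0.42, 2 of 11 called higher), S100 and alarmin genes (0.34) and lipid genes (0.07) were higher, and heat shock (-0.32), ribosomal (-0.07) and mitochondrially encoded genes (-0.12) lower. All had adjusted p = 0.779 with an estimated correlation. The lower heat shock values rest on donor 1, with medians of -0.36 in CD8 T-like, -0.55 in NK-like and -0.71 in B-like cells, against 0.12, 0.12 and 0.18 in donor 2 and 0.031, -0.085 and 0.17 in donor 3.

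CSF held fewer monocyte-like and more CD4 T-like sorted cells than blood in both donors. Monocyte-like cells made up 49.41% of blood and 4.37% of CSF cells in donor 4, and 86.18% and 40.58% in donor 5, a mean difference of -45.33 percentage points (SD 0.394, n = 2 donors). CD4 T-like cells went from 12.82% to 56.05% and from 3.42% to 15.50%. Dendritic cell-like cells made up 2.49% of blood and 2.65% of CSF cells in donor 4, but 0.943% and 30.55% in donor 5. A macrophage-like cluster, led by C1QC, C1QB, SELENOP, FCGBP, TREM2 and SPP1, held 242 of the 246 monocyte-like cells of CSF in donor 4 (98.4%) and 240 of 267 in donor 5 (89.9%). It held 0 of 2129 and 0 of 3394 blood cells, which allows shares of up to 0.141% and 0.0884%. Blood monocyte-like cells lay in classical and nonclassical clusters, so the monocyte-like comparison sets CSF macrophage-like cells against blood monocytes. Regulatory T-like cells were 299 in the CSF of donor 4 and at most 7 in each other library. With 2 pairs the shares were not tested.

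In monocyte-like cells, CSF showed genes of resident macrophages that were nearly absent in blood. APOE (ENSG00000130203, chromosome 19, 44905754 to 44909393), a lipid carrier, rose from 0.601 ± 0.310 to 2174 ± 577 CPM (SD, n = 2), a log2 fold change of 11.86 (SE 0.58), and APOC1 rose by 11.24 (SE 0.56). The selenium carrier gene SELENOP had a ratio of 20000 (95% counting interval 3580 to 789000), FCGBP 6240 (2130 to 30300) and the osteopontin gene SPP1 16000 (4430 to 132000). With 0 counts in blood, APOC2 was at least 2480-fold higher, the transcription factor gene BHLHE41 at least 1960-fold, PDGFB at least 758-fold, the dendritic cell marker CLEC9A at least 527-fold and IGSF21 at least 390-fold. The vasoactive peptide gene ADM fell, at -5.66 (SE 0.51), as did PADI4, which encodes a protein citrullinating enzyme, at -5.45 (SE 0.50), CRISPLD2 at -5.01, CYP1B1 at -4.74, and the neutrophil and monocyte alarmin gene S100A12, from 1238 ± 500.3 to 35.9 ± 49.0 CPM. MTMR11, CES1, AQP9, FOLR3 and MGST1 had values from -4.73 to -4.48. Each named gene moved the same way in 2 of 2 donors. CLEC9A was also among the leading genes of a dendritic cell-like cluster, and whether its RNA came from other cells was not tested.

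Inflammasome-related genes went both ways in CSF monocyte-like cells. IL18 (26.7 ± 0.242 to 279 ± 37.6 CPM) rose by 3.38 (SE 0.34), and IL1B (17.7 ± 6.45 to 83.7 ± 38.1 CPM) by 2.22 (SE 0.30). CASP1 fell, at -1.32 (SE 0.32, adjusted p = 0.000854), and NLRP3 had -0.02 (SE 0.29, adjusted p = 0.970) at a mean of 43.7 CPM. VEGFB and VEGFA, growth factor genes, rose by 4.08 (SE 0.33) and 1.35 (SE 0.30). S100A8 fell, at -3.90 (SE 0.43), and so did S100A9 (ENSG00000163220, chromosome 1, 153357854 to 153361027), from 16630 ± 3409 to 937 ± 669 CPM. IL6ST, which encodes the shared signalling chain gp130, had 0.73 (SE 0.30, adjusted p = 0.0566). SOCS3 had 0.51, IL11RA -0.50, NFKB1 -0.29, STAT3 -0.19, PYCARD -0.14 and NFKBIA 0.01, none past the threshold. The sign of SOCS3 depended on the donor, with 1.73 without donor 4 and -1.30 without donor 5.

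In total 3464 of 11785 genes were called in monocyte-like cells by edgeR (1843 higher, 1621 lower, 4585 at an unadjusted p under 0.05), and 3449 moved the same way in both donors. DESeq2 called 1691. The fit has 1 residual degree of freedom and the spread rests on information pooled over genes. Of 73 named genes that passed, 55 were in the fit without genes over 10 times higher in another class, and 0 of these were lost. Of 25 gene lists, 15 were called, 11 higher and 4 lower, and every call was lost with an estimated correlation (adjusted p from 0.477 to 0.722). Medians were the same to the second decimal with genes at 0 in a group set at their bounds, in all 15.

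Of 16 border macrophage and microglia genes measured, 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 4.71 and adjusted p = 0.477 with an estimated correlation. Among them GPR34 had 5.21 and the folate receptor gene FOLR2 4.79, the receptor kinase gene AXL a ratio of 1320 (364 to 11000), and P2RY13 fell at -1.06. Of 26 lipid handling genes, 17 were higher and 4 lower (median 1.16), with the oxidised lipoprotein receptor gene OLR1 at 8.94. Of 17 complement genes, 12 were higher and 1 lower (median 1.77), with C1QC at 9.81, C1QB at 7.47, VSIG4 at 6.39 and C3 at 5.91. Both lists had adjusted p = 0.477 with an estimated correlation. Of 16 MHC class II genes, 13 were higher and 1 lower (median 2.50, adjusted p = 0.507 with an estimated correlation), with HLA-DQA1 at 4.65, HLA-DOA at 4.16, HLA-DQB1 at 3.05 and HLA-DPB1 at 2.88. Adjusted over the list alone, the counts of these last 3 lists were the same. The macrophage-like cluster stands for nearly all the CSF cells behind these values and for no blood cell. The markers of the macrophage class are all members of the border macrophage list. Naming clusters by them favoured the direction of that list, which is no independent result.

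Of 19 inflammatory cytokine genes, 12 were higher and 2 lower (13 and 2 adjusted over the list alone, median 2.32, adjusted p = 0.477 with an estimated correlation). The chemokine gene CCL2 had 6.26, EBI3 6.66, IL10 5.21 and the gp130 cytokine gene OSM 4.94. Of 27 immediate-early genes, 10 were higher and 5 lower (11 and 6 adjusted over the list alone, median 0.71, adjusted p = 0.722 with an estimated correlation), with NR4A3 at 5.57, EGR3 at 4.77 and EGR2 at 4.46. Of 17 heat shock genes, 6 were higher and 0 lower (7 over the list alone, median 0.72, adjusted p = 0.513 with an estimated correlation), with HSPB1 at 3.50 and HSPE1 at 1.47. Of 9 T-cell activation and residency genes, 7 were higher (median 5.47, adjusted p = 0.477 with an estimated correlation), with RGS1, a regulator of G-protein signalling, at 8.93, and with the T-cell receptors CD28 at a ratio of 280 (94.1 to 1370), CD69 at 297 (80.2 to 2480) and CTLA4 at least 170-fold higher.

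T-cell markers moved with these last groups. All 6 pan-T markers measured in monocyte-like cells were higher (median 2.98, adjusted p = 0.621 with an estimated correlation), and 4 of 8 cytotoxic genes were higher and 1 lower (median 1.56, adjusted p = 0.513 with an estimated correlation). Without donor 4, CD3D had -3.51, TRBC1 -0.33 and TRAC -4.20, so their direction came from donor 4. Cytotoxic gene CST7 had 4.68, GZMA 3.23 and CCL5 1.99, with 0.76 and 0.32 for GZMA and CCL5 in donor 5. All 6 neutrophil markers fell (median -3.98, adjusted p = 0.477 with an estimated correlation), among them CSF3R at -1.99, and 8 of 12 classical monocyte markers fell and 1 rose (median -1.55, adjusted p = 0.477 with an estimated correlation). Classical clusters were named by these 12 markers, so their fall is no independent result. Of 10 S100 and alarmin genes, 7 fell (8 over the list alone, median -1.08, adjusted p = 0.477 with an estimated correlation), with ANXA1 at -1.21. Of 21 inflammasome genes, 7 fell and 2 rose, also when adjusted over the list alone (median -0.61, adjusted p = 0.0373, and adjusted p = 0.513 with an estimated correlation). MEFV, the pyrin gene, had -3.13 and the sensor gene NLRP1 -2.22, and the rises were IL18 and IL1B. Ribosomal genes were called as higher at a median of 0.47 (adjusted p = 0.684 with an estimated correlation) with 3 of 78 members passing and 0 when adjusted over the list alone. Lists not called included NF-kB (3 higher and 8 lower of 25), gp130 and STAT3 (2 and 6 of 24), interferon-stimulated genes (7 and 2 of 30) and oxidative phosphorylation (0 of 36).

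In CD4 T-like cells, single genes differed between CSF and blood. No gene list stayed called with an estimated correlation, a setting that 1 residual degree of freedom leaves too weak to decide. CXCR3 (ENSG00000186810), the receptor for interferon-induced chemokines, rose from 17.9 ± 1.10 to 80.5 ± 0.516 CPM (SD, n = 2), a log2 fold change of 2.19 (SE 0.28). The chemokine gene CCL5 rose by 2.04 (SE 0.20) and the activation-induced phosphatase gene DUSP2 by 2.40 (SE 0.23). CYP51A1 (ENSG00000001630, chromosome 7, 92112151 to 92134803) rose by 2.62 (SE 0.30), SQLE by 2.45, MVD by 2.23, HMGCS1 by 2.15 and INSIG1 by 2.04, enzymes and a regulator of cholesterol synthesis. IL6ST (ENSG00000134352, chromosome 5, 55935095 to 55994993) fell from 138 ± 9.60 to 65.7 ± 11.3 CPM, at -1.17 (SE 0.20, adjusted p = 6.33e-07). MYLIP, TMIGD2, ACTN1, HEXIM1, AC007952.4 and H2AFX lay between -2.01 and -1.79. Each of these moved the same way in 2 of 2 donors. The mix of CD4 T-like clusters differed too: a naive-like cluster, led by CCR7, LEF1 and TCF7, held 134 of 273 blood and 74 of 3158 CSF cells in donor 4, and 32 of 116 and 1 of 102 in donor 5.

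Myeloid genes fell in the same cells. S100A9 went from 176 ± 44.9 to 7.94 ± 6.56 CPM, at -5.20 (SE 0.26), with S100A8 at -5.42 (SE 0.33), AIF1 at -2.95 (SE 0.27) and the lysozyme gene LYZ at -2.52 (SE 0.30). Myeloid cells held 53.5% and 90.7% of the UMIs of the blood libraries and 10.1% and 45.8% of those of CSF. Over the 10 libraries, the measured S100A8 level in CD4 T-like cells was 0.522 to 2.03 times (median 1.19) that predicted from the other monocyte markers found in them, and S100A9 was 0.713 to 2.23 times (median 1.59). IGKC, an immunoglobulin gene, was higher by 2.43 (SE 0.25). Of the other fixed genes, SOCS3 fell (-1.24, SE 0.25) but had 0.21 without donor 4, and NFKBIA (-0.57, adjusted p = 0.0812), STAT3 (-0.31), NFKB1 (-0.35), IL11RA (-0.21), PYCARD (0.49), CASP1 (0.42) and VEGFB (0.37) did not pass.

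In CD4 T-like cells, edgeR gave the spread pooled over genes full weight, so SE and p do not reflect the spread of single genes between donors. edgeR called 245 of 7935 genes in CD4 T-like cells (92 higher, 153 lower, 1007 at an unadjusted p under 0.05), of which 231 moved the same way in both donors. The count was 12 by DESeq2 and 76 without the donor block. Without donor 4 it was 49, and without donor 5 it was 771, in fits where the lone pair is assumed to vary like the other libraries. Of 53 named genes that passed, 44 no longer did by DESeq2. Without donor 4, 3 of the 53 changed sign: SOCS3 had 0.21, GZMK -0.082 and RPL37 0.016. The fit without genes over 10 times higher in another class held 37 of the 53, of which 1 no longer passed. Of 23 gene lists, 11 were called, 4 higher and 7 lower, and each was lost with an estimated correlation, at adjusted p = 0.587, or 0.680 for ribosomal genes.

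Of 15 naive and central memory T genes, 8 fell and 0 rose (13 adjusted over the list alone, median -0.66, adjusted p = 0.587 with an estimated correlation), with the chromatin organiser gene SATB1 at -1.34 (SE 0.20), TXK at -1.03, the transcription factor gene TCF7 at -0.96 and the lymph node homing receptor gene CCR7 at -0.85. In a single CD4 T-like cluster, led by AQP3 and CCR6, TXK had 0.039 and CCR7 0.37. Of 22 gp130 and STAT3 genes, 7 fell and 1 rose, also when adjusted over the list alone (median -0.31, adjusted p = 0.587 with an estimated correlation), with PIM2 at -1.33 (-0.23 in donor 5) and MYC at -1.09. Of 19 NF-kB genes, 4 fell (5 over the list alone, median -0.04, adjusted p = 0.587 with an estimated correlation), with IER3 at -1.80, NFKBIZ at -1.43 and BIRC3 at -0.80. Mitochondrially encoded genes fell in 10 of 13 cases (11 over the list alone, median -0.71, adjusted p = 0.587 with an estimated correlation), at -1.19 for MT-CYB, with -1.78 in donor 4 and -0.56 in donor 5. Ribosomal genes fell in 4 of 77 cases (11 over the list alone, median -0.14, adjusted p = 0.680 with an estimated correlation).

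Of 10 cytotoxic effector genes, 5 rose (median 0.89, adjusted p = 0.587 with an estimated correlation), with CST7 at 1.81 and GZMA at 1.55. GZMK had 1.55, but -0.082 without donor 4 and -0.23 in the single cluster. Of 9 MHC class II genes, 5 rose (median 0.99, adjusted p = 0.587 with an estimated correlation), with HLA-DRB1 at 2.01 and HLA-DQB1 at 1.47, and of 15 T-cell activation genes, 4 rose (7 over the list alone, median 0.54, adjusted p = 0.587 with an estimated correlation), with the retention marker CD69 at 1.59 and the chemokine receptor CXCR6 at 2.50. The checkpoint receptor gene PDCD1 had 1.57 (adjusted p = 0.0743). The part of free RNA from other cells in these values was not measured. For the cytotoxic and MHC lists the number higher was the same when adjusted over the list alone, and 1 MHC gene was then lower. Cytokine genes were called with 1 of 7 higher, which was CCL5. The inflammasome list was not called (median -0.04, adjusted p = 0.595), with 1 of 11 genes lower, TXNIP at -0.63 (SE 0.17), a gene singled out after its value was seen. Classical monocyte markers fell in 4 of 5 cases (median -3.17), with FCN1 at -4.54 and MNDA at -5.48, and S100 and alarmin genes in 3 of 9. The S100 list's median of 0.04 differed in sign from its mean of -1.19 and from its test. The cytokine, monocyte marker and S100 lists had adjusted p = 0.587 with an estimated correlation, and their counts were the same when adjusted over the list alone.

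**Figure D3:**
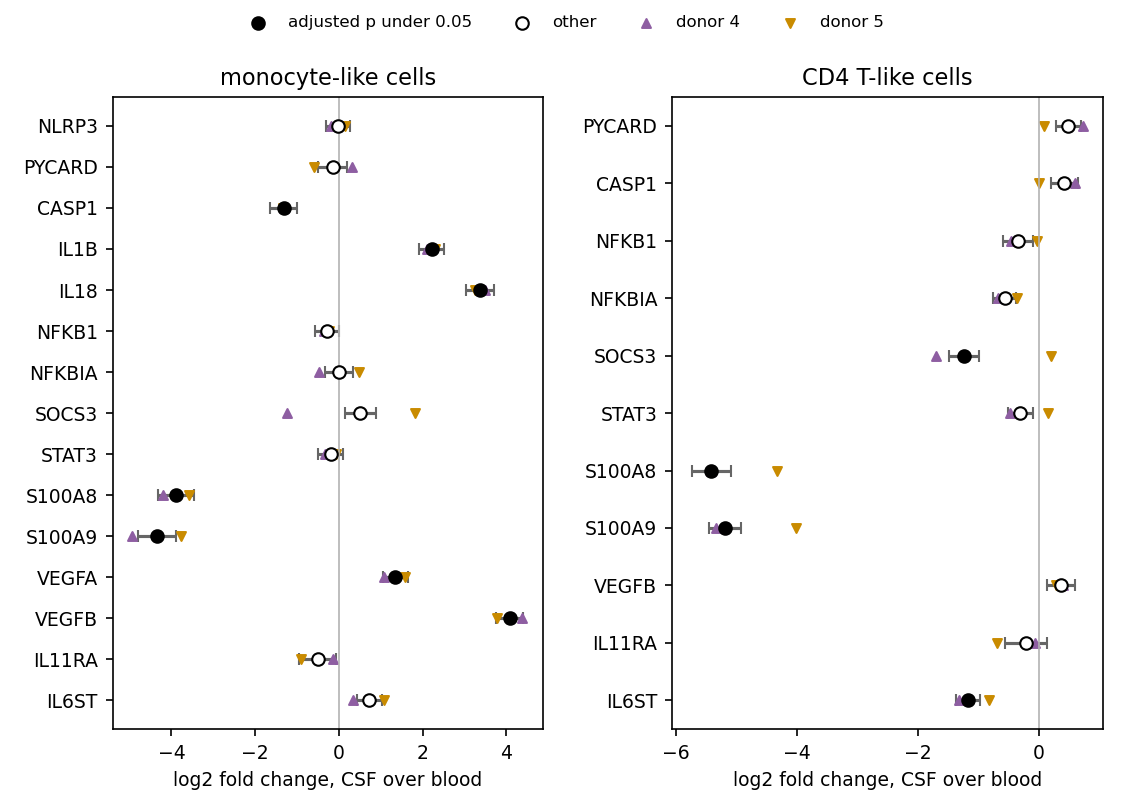
Log2 fold change of CSF against blood with its SE for the genes fixed in advance, in monocyte-like and CD4 T-like cells (n = 2 donors); filled points have an adjusted p under 0.05 and triangles give donors 4 and 5. IL18 stands at 3.38 and S100A8 at -3.90 in monocyte-like cells, and NLRP3 at -0.02.

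In plasma cell-like cells, CSF differed from blood in antibody constant genes among others. IGHG1, the IgG1 heavy chain, rose by 4.03 (SE 0.69, adjusted p = 0.0461), while IGHA2 had -8.65 (SE 0.78) and the light chain gene IGLC1 -6.79 (SE 1.03, n = 2 donors). PLAC8 fell, at -4.18 (SE 0.51), and APOE, with a ratio of 130 (23.1 to 5170), and ACY3, with 64.0 (17.4 to 532), were higher. APOE RNA was also abundant in monocyte-like cells of CSF, and free RNA from them was not tested as its source. The fit without genes over 10 times higher in another class held 5 of these 6 genes. edgeR called 23 of 4394 genes (15 higher, 8 lower), DESeq2 24, and edgeR 70 and 89 without donor 4 or 5. Of the 23, 16 were among the 70. IGHA2, APOE and ACY3 no longer passed without donor 4, nor did APOE, ACY3 and IGHG1 without the donor block. The libraries held 24 to 47 plasma cell-like cells, and 97 of 136 barcodes were shared with another library of the experiment. Of the 136, 70 had a deeper copy in another library. Cells deep enough for the IL11RA share numbered 14 and 27 in blood and CSF of donor 4, and 11 and 13 in donor 5. Without the donor block 12 genes were called. Of 20 lists 14 were called, all lost with an estimated correlation (adjusted p of 0.583 or more), and of 12 MHC class II genes 3 were higher (10 adjusted over the list alone, median 1.51, adjusted p = 0.583 with an estimated correlation).

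In dendritic cell-like cells, CSF showed less RNA of TNF and more of some interferon-stimulated genes. TNF fell from 61.3 ± 0.369 to 4.71 ± 0.104 CPM (SD, n = 2), at -3.67 (SE 0.40), the nuclear lamina gene LMNA fell at -4.24 (SE 0.31) and S100A12 at -3.14 (SE 0.31). The prostaglandin D synthase gene PTGDS had a ratio of 105 (18.8 to 4170), the interleukin-7 receptor gene IL7R 23.6 (7.98 to 115), and BHLHE41 was at least 14.6-fold higher. Of these 6 genes, S100A12, PTGDS and IL7R are over 10 times higher in another class. edgeR called 396 of 8235 genes (241 higher, 155 lower), DESeq2 33, and 83 were called without the donor block. The spread pooled over genes had full weight in the edgeR fit here too. Of 21 lists, 11 were called, each lost at adjusted p = 0.634 with an estimated correlation. Of 25 interferon-stimulated genes 7 rose (11 adjusted over the list alone, median 0.74), of 10 border macrophage genes 6 rose (also 6 over the list alone, median 1.09), and of 12 complement genes 4 rose (6 over the list alone, median 0.81). Of 7 inflammatory cytokine genes 2 rose (3 over the list alone, median 0.73), and of 10 S100 and alarmin genes 4 fell (also 4 over the list alone, median -0.50).

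Across genes, the changes after IL-11 and those between CSF and blood were nearly uncorrelated. Pearson's r was 0.0166 over 11033 genes in monocyte-like cells (Spearman's rho 0.0744) and 0.00716 over 7812 genes in CD4 T-like cells (rho 0.0269). These are correlations across genes, which are not independent replicates. The IL-11 genes were not tested as a list in CSF, since fewer than 10 were called in any direction.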

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

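The tests with robust empirical Bayes, a single CD4 T-like cluster, barcodes kept in their deepest library and genes of other classes left out were chosen after the result was seen. Of 228 named values, 148 passed their threshold, and over all alternatives 3543 values were recomputed. Of these, 3165 kept their direction and their side of the threshold, 241 lost the threshold and 73 passed it anew. Another 53 changed sign with neither the main nor the alternative value past the threshold. The other 11 changed sign with either value past it and are called reversed. Where one of the counts below differed by more than 1.5 times or a value reversed, the value is given, and the cause was not tested.

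In monocyte-like cells after IL-11, the count of 0 became 13 without a filter on low counts, 2 to 191 with a donor left out, 1 at Leiden resolution 2, 2 with counts thinned, 10 in classical monocyte-like clusters alone and 1 with robust empirical Bayes. In CD4 T-like cells the 4 calls became 0 with relative log expression size factors, by DESeq2, without the donor block (no replicate block), with doublets kept, at Leiden resolution 2, with counts thinned and with all 10 libraries in 1 fit. They became 18 without the filter, 10 without genes over 10 times higher in another class, and 0 to 44 with a donor left out. In the other classes the 12 calls became 1 by DESeq2, 79 without the filter, 0 with no donor block, 19 to 62 with a donor left out, 0 thinned, 20 with robust empirical Bayes and 26 without genes of other classes (25 in plasma cell-like and 0 in B-like cells, from 9 and 3). They became 3 with at least 500 genes per cell and 2 with barcodes in their deepest library, but in both settings plasma cell-like cells, which held 9 of the 12, had too few cells for a fit, so those 9 were not retested. A minimum of 50 cells per library could be met in CD8 T-like cells (0 calls) and B-like cells (18 calls, with donor 3 left out by that minimum), and in no other class outside the main pair. Taken alone, the 9 calls of plasma cell-like cells became 1 by DESeq2, 51 without the filter, 0 with no donor block, 2 to 42 with a donor left out, 5 under 10% mitochondrial UMIs, 0 thinned and 15 with robust empirical Bayes. The 3 of B-like cells became 0 by DESeq2, 12 without the filter, 0 with no donor block, 3 to 18 with a donor left out, 0 with doublets kept, 0 thinned and 1 with barcodes in their deepest library. The 0 of CD8 T-like cells became 11 without the filter, 0 to 32 with a donor left out, 2 with robust empirical Bayes, and 1 each with doublets kept, at Leiden resolution 2, with barcodes in their deepest library and without genes of other classes. The 0 of NK-like cells became 5 without the filter, 0 to 16 with a donor left out and 4 at Leiden resolution 2. The interaction count of 0 became 1 without the filter and 0 to 1 with a donor left out.

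In CSF against blood, the 3464 calls of monocyte-like cells became 1691 by DESeq2. The 245 of CD4 T-like cells became 12 by DESeq2, 76 with no donor block, 49 to 771 with a donor left out, 104 thinned, 453 with all 10 libraries in 1 fit and 106 in a single cluster. The 23 of plasma cell-like cells became 151 without the filter, 12 with no donor block, 70 to 89 with a donor left out, 56 under 10% mitochondrial UMIs and 98 thinned. The 396 of dendritic cell-like cells became 33 by DESeq2, 83 with no donor block and 182 thinned. Fits with a lone pair of CSF and blood libraries take their spread from the other libraries. In dendritic cell-like cells no such fit had residual degrees of freedom, so none was made. Classical monocyte-like clusters alone could not be fitted in CSF, where donor 4 had 3 such cells, nor could plasma cell-like cells with barcodes kept in their deepest library or with at least 500 genes per cell, for lack of 20 cells.

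The 3 gene lists called in monocyte-like cells after IL-11, the 15 in monocyte-like cells of CSF and the 11 in CD4 T-like cells of CSF became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry. The 3 became 0 with no donor block as well.

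Among the named genes, values reversed with a donor left out, or in the single cluster, for a few. Other called genes are not covered here. In CD4 T-like cells after IL-11, IL1B was -1.10 without donor 1 (adjusted p = 0.0180), 0.68 without donor 2 (adjusted p = 0.0142) and 0.68 without donor 3 (adjusted p = 1). In monocyte-like cells of CSF, values without donor 4 and without donor 5 were 1.73 and -1.30 for SOCS3, -3.51 and 4.05 for CD3D, -0.33 and 2.96 for TRBC1, and -4.20 and 3.31 for TRAC. In CD4 T-like cells of CSF they were 0.21 and -1.69 for SOCS3, -0.082 and 2.26 for GZMK, and 0.016 and -0.87 for RPL37, and the single cluster gave -0.23 for GZMK, 0.039 for TXK and 0.37 for CCR7. Without donor 4 the median of all genes in monocyte-like cells of CSF shifted by -0.12. With relative log expression size factors and by DESeq2 it shifted by less than 0.1.

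The monocyte-like share in CSF minus blood, -45.33 percentage points, was -47.0 with at least 500 genes per cell, -45.9 under 10% mitochondrial UMIs and -45.8 with barcodes in their deepest library, moves larger than the donor spread of 0.394. Without thinning, IL11RA was found in 4.30% of monocyte-like and 8.29% of CD4 T-like cells. Depth limits these shares, since most sorted cells held no IL11RA UMI, and it limits plasma cell-like and dendritic cell-like fits, where some libraries held few cells.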

Other observations

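The tests of handling stress, of exchanged labels in donor 1, of shared barcodes by chance and of other splits of the libraries were chosen after the result was seen.

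Monocyte-like cells of donor 1 moved against those of donors 2 and 3 after IL-11, with a correlation across 5418 genes, which are not independent replicates, of -0.537 (SE 0.0342) between donor 1 and the mean of the others, and 0.391 between donors 2 and 3. Without donor 1, 191 genes were called (122 higher, 69 lower), among them 12 heat shock genes and 7 nonclassical monocyte markers, all higher, and 165 of the 188 with a value in donor 1 had the opposite sign there. The nonclassical share fell in donor 1, from 37.9% to 17.3%, and went from 35.8% to 46.6% and from 26.6% to 49.3% in donors 2 and 3, and while the correlation of -0.289 (SE 0.0189) within the nonclassical cluster argues against this share as the whole cause, that of -0.0313 (SE 0.0350) within classical clusters leaves it open as a part. Within the nonclassical cluster donor 1 opposed mainly donor 2 (-0.350, against -0.113 with donor 3), and donors 2 and 3 correlated at 0.186. A difference in handling stays open, since heat shock medians of donor 1 went against the others by over 0.5 in 2 of 5 other classes and were lower in all 5 (by 0.35 to 0.83). Exchanged labels, used as given, cannot be told apart from a different response of that donor, which was not tested, since 3 of 5 other classes gained calls with the labels of donor 1 exchanged, but so did 4 with those of donor 2 and 3 with those of donor 3, and the 9 plasma cell-like calls, which rest in part on shared barcodes, became 0.

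The 6 libraries of the IL-11 experiment can be split into 3 and 3 in 10 ways with the real one, too few for a share under 0.05. Genes called were 0 in monocyte-like cells (highest other split 412, 10 of 10 splits with as many), 4 in CD4 T-like cells (20, 5 of 10), 12 in the other classes (33, 6 of 10) and 0 for the interaction (174, 10 of 10). Lists called were 3 in monocyte-like cells (12, 10 of 10) and 0 in CD4 T-like cells (10, 10 of 10). The real split and 3 others part the libraries of each donor, and the other 6 keep both libraries of 2 donors together, so that with the donor block a single donor informs their class fits; the 20, 174 and 10 come from these. Among the 3 that part each pair, the highest values were 412, 10, 33 and 0 for genes and 12 and 9 for lists, in the same order. The split with 412 is the one in which the labels of donor 1 are exchanged, so it points to a structure of the samples, the opposed monocyte-like changes of that donor.

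Sterol synthesis genes were higher in CD4 T-like cells of CSF than of blood. Of 19 genes measured from a list written after 6 of them had been seen, all 19 were positive and 12 passed, with a median log2 fold change of 1.44, and among the 13 not first seen all 13 were positive and 6 passed (camera adjusted p = 1.26e-16, adjusted p = 0.247 with an estimated correlation). Within a single CD4 T-like cluster the median over 14 genes was 0.994 times that of the whole class (1.66 against 1.67), which argues against the mix of CD4 T-like subsets as the cause, and 0 of the sterol genes were over 10 times higher in another class, which argues against free RNA. In other classes 17 of 24 genes passed as higher in monocyte-like, 7 of 21 in dendritic cell-like and 1 of 16 in plasma cell-like cells, and the list tests there were lost with an estimated correlation (adjusted p = 0.187, 0.132 and 0.132). A difference between the fluids and the time and handling before sorting stay open, and neither was tested.

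Plasma cell-like cells share barcodes between libraries of the same experiment, 152 of 252 in the IL-11 experiment and 97 of 136 in the fluid experiment. Over all cells, 21 pairs of libraries within an experiment shared 828 barcodes and 24 pairs between experiments shared 53, a rate 20.6 times as high per pair of cells, which argues against chance use of a barcode by different cells. Among 316 shared pairs from 49 plasma cell-like barcodes, 97.5% had the same leading light chain and isotype in both libraries, against 20.7% when matched at random. This is consistent with RNA of the same cell counted in several libraries sequenced together, and results of plasma cell-like cells rest in part on such copies. In the fluid experiment 107 of 482 macrophage-like, 70 of 435 dendritic cell-like and 210 of 1003 unnamed barcodes were shared. All 210 unnamed ones were the shallower copy (median 588.5 UMIs), against 0 of the 107 and 0 of the 70. The CSF libraries of donors 4 and 5 shared 206 barcodes, at a median of 613 UMIs in donor 4 and 13157.5 in donor 5. Unnamed cells did not enter the tests. A test on heavy-chain variable segments could not be made, since 1 pair had enough UMIs, and the chains were compared in its place.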
